A study of Pongo abelii with 6 samples.

How the data were processed

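RNA-seq of 6 libraries was analysed, 3 of each of 2 orangutan induced pluripotent stem cell lines. Per the labels' protocols, cells were grown on Matrigel in iPS-Brew medium with the small molecules IWR1 and CHIR, and libraries were made from total RNA after ribosomal RNA depletion. The labels' treatment field says that the cells were differentiated and their genotype field names small RNA, while titles and protocols describe undifferentiated cells and total RNA; the groups used here are the lines given in the titles. The values are TPM per transcript, per the file headers, scaled by the authors so that all 6 columns have the same sum, which keeps no read depth. The authors' flag for HERV entries and their flag for expressed HERV transcripts are marks of another kind, each 0 or 1, per the file headers, and the rule behind the second is not given in the sources used here. Trimmomatic 0.39, FastQC 0.11.9, STAR and StringTie were used upstream, per the submitters' processing notes, without their roles. The quantifier, genome build and annotation release are not given in the sources used here. Matched small RNA libraries were not analysed here.

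Gene symbols came from the RefSeq gene table of assembly NHGRI_mPonAbe1-v2.0, used only for names and for grouping genes by chromosome. Accessions were matched without their version, which named 22113 of 43705 RefSeq transcripts (50.6%), 3321 of them with the version too, and TPM was summed over the transcripts of each of 15205 genes. StringTie transcripts, which held 71.7% to 81.2% of each TPM total, carry no symbol.

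The main test was limma-trend on log2(TPM + 1) without a block, Djasinga minus Dokana, on transcripts or genes with at least 1 TPM in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. Gene lists with at least 5 tested members were tested with camera (inter-gene correlation 0.01, and estimated) and fry. The 29 lists, the tests and the rule for named genes were fixed before the data were examined. The rule names POU5F1, NANOG, SOX2, LIN28A, LIN28B and DPPA4, the 10 largest changes in each direction past the threshold with a mean of at least 5 TPM in the higher line, no overlap of libraries and a symbol that is not a LOC number, up to 4 called members of each list, all called members of the LIN28/let-7 list, and Y-linked genes and XIST. LOC genes, other called transcripts with a symbol, and uncalled members given for their levels were chosen after their values were seen.

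The plan spoke of genes, and the table held transcripts. Transcripts were taken as the main level and gene sums as a further result after both had been run and their counts seen, so that choice, and the use of the rule for named genes on transcripts, was not blind. The replicate number was taken to pair libraries across the lines because the labels give it under a batch tag; this was settled after the fits with and without the block had been seen. The data show no common pairing: deviations from the line mean of same-numbered libraries correlated by -0.108, -0.0995 and 0.167 across transcripts.

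Tested on simulated data with the spread of the real libraries, the test recovered 24%, 76%, 90% and 92% of 50 transcripts changed by 1, 2, 3 and 4 on the log2 scale among 22561, and 44%, 90%, 90% and 94% among 6255 genes; with no change it called 0. Of all calls in these simulations, 10 of 151 transcripts and 6 of 165 genes were false. The simulated noise was independent between transcripts or genes, with no deviations shared within a library and no floor at 0. These rates may therefore not hold for the real libraries. First fits to the real data were looked at before this test was written. Alternatives covered the block, leaving out each library, low-value filters, median-ratio and quantile scaling, the pseudocount, limma settings, a minimum fold change of 1.5, gene classes and list tests. Further ones were chosen after seeing the data. Some left out the most abundant transcript, snRNA and snoRNA transcripts or repeated values, or combined the block with median-ratio scaling. Others ran fry with the block, or for change in either direction after median-ratio scaling. Others repeated the list tests without Djasinga replicate 3 or required the accession version. Single values were also tested within pairs of same-numbered libraries by exact sign changes (3 pairs, smallest possible p 0.25). Random gene lists (10000 per list, matched on mean expression in 50 bins) were drawn with a fixed seed. The low p53 targets of Djasinga replicate 3, and less so of Dokana replicate 3, were found by looking through all lists library by library, and a second p53 target list and a list of immediate-early genes were then written, without genes whose values had been seen. Some single-gene results are not reported here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.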

Results

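RNA was measured in induced pluripotent stem cells (adult cells reprogrammed to a state resembling the early embryo) of the Sumatran orangutan, Pongo abelii. There were 2 lines, Dokana and Djasinga, with 3 libraries of ribosomal-RNA-depleted total RNA each. The titles number the libraries of a line as biological replicates. The labels tie them to passages of its culture, and the design text calls the lines replicates and the passages technical replicates. P-values and SDs therefore measure the spread between passages and not the spread between animals. Each library was given as TPM (a length-corrected share of the library's transcripts) for 58409 transcripts: RefSeq accessions, assembled StringTie transcripts and 29 entries for HERV, an endogenous retrovirus group. TPM keeps no read depth, so the depth is unknown, and 20226 to 24300 transcripts reached 1 TPM in a library. Levels of genes are sums over transcripts paired with a symbol, and transcripts without a symbol may hold further RNA of the same genes. The series title names HERVH, LIN28A and let-7. Levels of the HERV entries, LIN28B, microRNA-processing genes and let-7 targets are therefore given beside the comparison of the lines. LIN28A had no named transcript, let-7 itself was not analysed, and the HERV entries are not labelled as HERVH.

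Both lines carried RNA of core and primed pluripotency genes, while markers of naive pluripotency were low. NANOG, a transcription factor of the pluripotent state, was at 78.3 ± 21.1 TPM in Dokana and 49.9 ± 21.1 in Djasinga (SD, n = 3), and SOX2, which acts with it, was at 51.3 ± 9.3 and 37.4 ± 5.69 TPM. SALL4 was at 45.2 ± 7.71 and 36.9 ± 1.32 TPM, and DNMT3B, a DNA methyltransferase high in early embryonic cells, at 76.4 ± 21.2 and 49.6 ± 14.1 TPM. CD24, a surface marker of the primed state, was at 152 ± 9.11 and 132 ± 24.9 TPM, at percentiles 99.0 and 99.1 of the 12871 named genes detected. It was the highest of the 8 primed markers paired with a symbol, whose median was 18.1 TPM in Dokana and 15.3 in Djasinga. Of 15 markers of naive pluripotency paired with a symbol, the highest mean was 1.30 TPM, for KLF5 in Djasinga, and KLF17 stood at 0.0530 ± 0.0196 and 0.0993 ± 0.0724 TPM. Of the lineage regulators SOX17 (endoderm), TBXT (mesoderm) and CDX2 (trophoblast), the highest mean was 0.0191 TPM, for TBXT in Dokana. Of other lineage markers, KRT18, a keratin of epithelial cells fixed here as an endoderm marker, was at 100 ± 12.1 and 129 ± 25.8 TPM. THY1, a surface protein fixed as a marker both of fibroblasts and of primed pluripotency, was at 61.3 ± 11.1 and 40.8 ± 16.7 TPM. The highest tested markers of neuroectoderm, mesendoderm and trophoblast were POU3F1 (4.92 ± 1.27 and 4.27 ± 1.68 TPM), CER1 (3.08 ± 0.329 and 1.95 ± 0.0843 TPM) and IGFBP3 (2.01 ± 0.790 and 5.02 ± 6.58 TPM). Of 9 core and 8 primed pluripotency genes tested, 0 passed the threshold over all genes or adjusted over the list alone (limma), and 1 and 0 had an unadjusted p under 0.05. The smallest adjusted p in the core list was 0.283, for USP44, a deubiquitinase. POU5F1, LIN28A, DPPA4 and XIST and the Y-linked genes had no transcript paired with their symbol and were not analysed here.

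**Figure D1:**
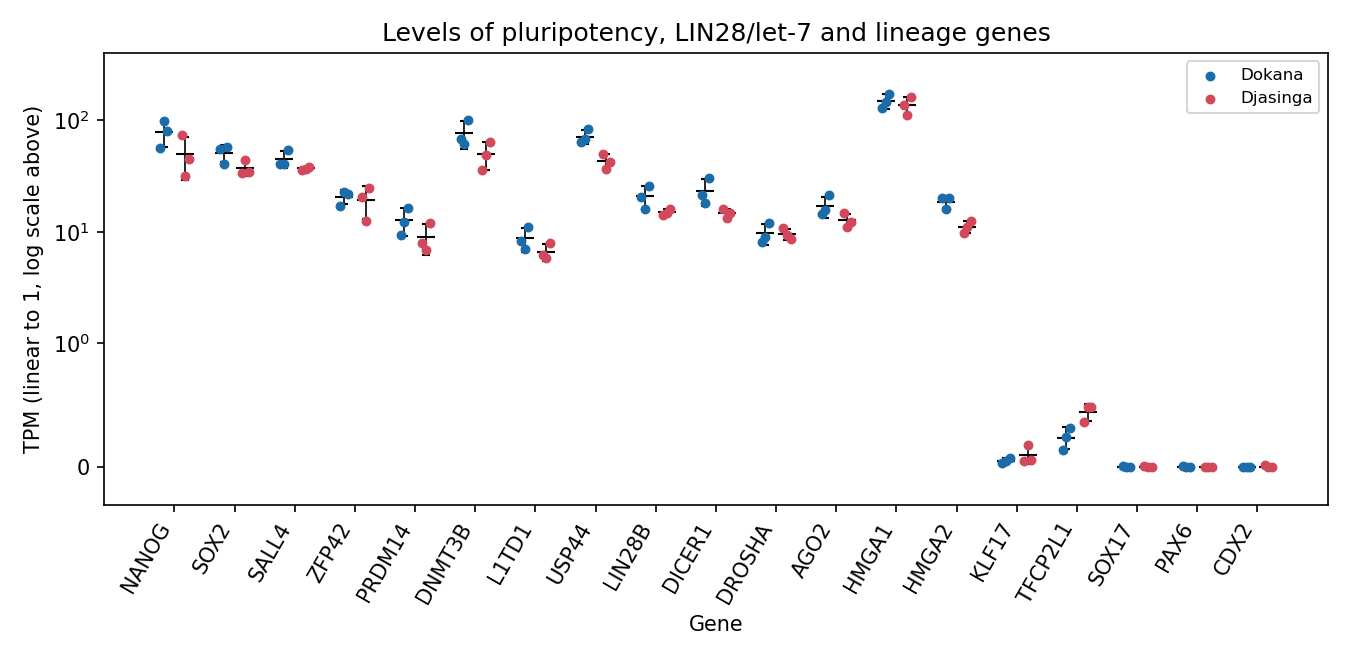
TPM (linear to 1, log scale above) of pluripotency, LIN28/let-7 and lineage genes in each library of Dokana (blue) and Djasinga (red). Points are libraries, and bars are the mean and SD of 3 libraries. NANOG to HMGA2 lie above 5 TPM in every library, and KLF17 to CDX2 lie below 1 TPM.

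Among genes of the LIN28/let-7 axis, LIN28B, which blocks the maturation of let-7 microRNAs, was at 20.8 ± 4.84 TPM in Dokana and 14.9 ± 1.06 in Djasinga (log2 difference -0.43, SE 0.21, limma adjusted p 0.350; -0.14 relative to the median gene, and -0.088 after median-ratio scaling, limma adjusted p 0.965). HMGA2 and HMGA1, chromatin proteins targeted by let-7, were at 18.7 ± 2.35 and 149 ± 21.9 TPM in Dokana and at 11.1 ± 1.35 and 137 ± 25.8 TPM in Djasinga. DICER1, which cuts microRNA precursors, was at 23.4 ± 6.35 and 14.7 ± 1.44 TPM, and DROSHA, which acts before it, at 9.71 ± 2.06 and 9.59 ± 1.09 TPM. HNRNPA1, a let-7 precursor-binding protein, was the most abundant of this list at 500 ± 79.2 and 342 ± 9.97 TPM. Of 11 members of the LIN28/let-7 and microRNA biogenesis list and 15 let-7 targets tested, 0 passed the threshold over all genes or adjusted over the list alone (limma). At an unadjusted p under 0.05 there were 3 and 2, all lower in Djasinga as was the median gene (-0.29), and after median-ratio scaling 0 and 0 lower and 1 and 0 higher.

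The lines differed at 232 of 22561 transcripts tested, 65 higher and 167 lower in Djasinga (limma on log2(TPM + 1), adjusted p under 0.05), all of them by at least 1 on the log2 scale, and 3272 had an unadjusted p under 0.05. The median transcript differed by -0.27 between the lines, so changes are also given relative to it. The transcript of POLR1H, a subunit of RNA polymerase I, was at 18.3 ± 3.02 TPM in Dokana and 0.466 ± 0.517 in Djasinga (SD, n = 3; log2 change -3.76, SE 0.29, -3.49 relative to the median, limma adjusted p 0.000919). The gene's other transcript had the opposite difference (2.55 on the log2 scale after median-ratio scaling), and POLR1H summed over its transcripts did not pass the threshold (log2 difference -0.22, limma adjusted p 0.487). RBM46, an RNA-binding protein with a role in germ cells, was at 20.5 ± 1.36 and 4.08 ± 2.48 TPM (-1.93 relative to the median, limma adjusted p 0.0289). A transcript of RPL38, a ribosomal protein, was at 20.2 ± 2.80 and 5.36 ± 1.09 TPM (-1.47 relative to the median, limma adjusted p 0.00952).

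Transcripts of SLC44A1 (a choline transporter), RNF10 (a ubiquitin ligase), ELOC (elongin C) and FAM72A were also lower in Djasinga, by -1.58, -1.48, -2.63 and -1.24 relative to the median (limma adjusted p 0.0120, 0.0145, 0.0498 and 0.0400). These and POLR1H, RBM46 and RPL38 were the 7 transcripts that met the rule for named genes, and 0 higher in Djasinga met it. Summed per gene and tested with all gene classes, 0 of the 7 passed the threshold (limma adjusted p 0.0793 for RBM46, the smallest). Among protein-coding genes alone, the sums of RBM46, ELOC and RNF10 passed (limma adjusted p 0.000529, 0.0194 and 0.0477), and none of the 3 after median-ratio scaling (0.117, 0.271 and 0.209). RBM46 had 1 named transcript, with the same log2 change of -2.20 (SE 0.35) as a transcript and as a gene among all classes, so its call did not end by summing. The other 9 transcripts past the threshold whose symbol is not a LOC number had a mean under 5 TPM in the higher line, and are named here after their values were seen. MSANTD3, SLC2A5 (a fructose transporter), N6AMT1, CABP1, MTHFD2L and SINHCAF were lower in Djasinga. ZNF302, a zinc finger gene, was higher, at 0.0799 ± 0.0597 TPM in Dokana and 3.45 ± 0.561 in Djasinga (log2 change 2.04, SE 0.19, 2.31 relative to the median, limma adjusted p 0.00288), as were RBIS (0.192 ± 0.333 and 3.28 ± 1.08 TPM) and PDPK1 (0.00609 ± 0.0105 and 1.76 ± 0.121 TPM), a kinase of insulin signalling. Assembled StringTie transcripts without a symbol made up 140 of the 232.

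**Figure D2:**
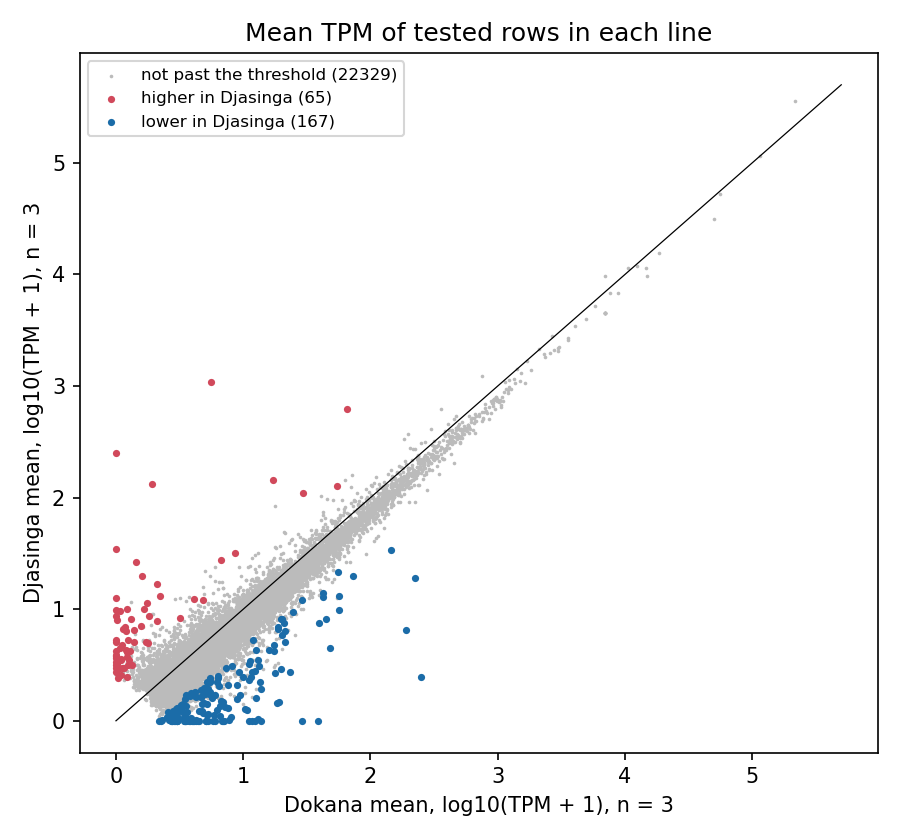
Mean log10(TPM + 1) of each tested transcript in Dokana (x axis) and Djasinga (y axis), 3 libraries each. Red points are the 65 transcripts higher and blue points the 167 lower in Djasinga, grey points those not past the threshold, and the line marks equal means. Most grey points lie below the line, as the median log2 change of -0.27 states.

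After median-ratio scaling, 178 transcripts were called, 72 higher and 106 lower, and 166 of the calls were shared; quantile normalization gave 72 higher and 88 lower, and leaving out the most abundant transcript 87 higher and 119 lower. ELOC, RBM46, MSANTD3, RNF10, FAM72A, N6AMT1 and SINHCAF then missed the threshold (adjusted p 0.0516 to 0.138). With the replicate number as a block, 152 transcripts were called, 52 higher and 100 lower, and ELOC (adjusted p 0.0917), RBM46 (0.0508) and FAM72A (0.0799) missed it among the 7, as did PDPK1 (0.0533), MSANTD3, SLC2A5, N6AMT1, CABP1, MTHFD2L and SINHCAF (0.0659 to 0.116). Without Dokana replicate 1, 2 or 3 the counts were 127, 130 and 100.

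Summed per gene, most genes called were small nuclear or nucleolar RNAs. Of 6255 genes with a symbol, 22 passed the threshold, 11 higher and 11 lower in Djasinga (limma), and 15 of them were snRNA or snoRNA genes, which made up 1035 of the genes tested (odds ratio 10.9, two-sided Fisher's exact test p 9.4e-08). The share called was 1.98% of 505 snRNA, 0.943% of 530 snoRNA, 1.98% of 101 lncRNA and 0.0983% of 5089 protein-coding genes. Tested alone, protein-coding genes gave 48 calls as deposited and 3 after median-ratio scaling. As deposited, the contrast between classes thus depends on the joint fit. After median-ratio scaling it remained in the joint fit, with 10 of 505 snRNA, 4 of 530 snoRNA and 4 of 5089 protein-coding genes called. Small RNA genes were not tested alone. Fisher's test also takes genes as independent, which copies that share reads are not. The snRNA LOC112131677 was at 4.61 ± 1.99 TPM in Dokana and 1082 ± 98.3 in Djasinga (SD, n = 3; log2 change 7.66, SE 0.30, 7.96 relative to the median gene, limma adjusted p 0.000180). LOC112130897 was at 64.8 ± 20.6 and 625 ± 81.9 TPM. The snRNA LOC112131683 was listed at 0 in all 3 Dokana libraries and stood at 122, 209 and 420 TPM in Djasinga replicates 1, 2 and 3. The lncRNA LOC100455393 went the other way, with 223 ± 32.2 TPM in Dokana and 17.9 ± 2.79 in Djasinga (log2 change -3.56, SE 0.19, limma adjusted p 0.000627), and the lncRNA LOC100936956 was at 15.4 ± 1.54 and 83.8 ± 18.6 TPM. SnRNA and snoRNA genes have near-identical copies elsewhere in a genome, and reads could have been split among them by the authors' quantification, so the values of single copies are uncertain.

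Of 5089 protein-coding genes, 5 were among the 22 genes called: LOC100431578, PDPK1 and ZNF302 higher, SLC2A5 and ZNF875 lower. LOC100431578, PDPK1 and ZNF302 each had 1 named transcript, as had the called snRNA and snoRNA genes. Their gene values are those of that transcript and add no separate evidence. Transcripts without a symbol may hold further RNA of these genes, so low values need not mean that the gene was silent. SLC2A5 summed over its transcripts was at 5.86 ± 0.296 TPM in Dokana and 1.92 ± 0.215 in Djasinga (log2 change -1.23, SE 0.17, -0.94 relative to the median, limma adjusted p 0.0437). Median-ratio scaling called 20 genes, 13 higher and 7 lower, of which 17 were shared, and SLC2A5 and ZNF875 were not among them (adjusted p 0.122 and 0.124). Quantile normalization gave 14 higher and 6 lower, and leaving out the most abundant transcript 11 higher and 7 lower. The replicate block called 5 genes, 4 higher and 1 lower: the snRNAs LOC112131677, LOC112131683, LOC112130897 and LOC112131459 and, lower in Djasinga, LOC100455393. Tested without other gene classes, protein-coding genes gave 48 calls, 9 higher and 39 lower, and after median-ratio scaling 3 calls, 3 higher and 0 lower. Without Dokana replicate 1, 2 or 3 or Djasinga replicate 1 or 3, 12, 9, 7, 10 and 7 genes were called.

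Gene groups fixed for this tissue passed no test of a common direction between the lines with all 6 libraries and the filter on low values. Of 29 lists, 17 had at least 5 tested members, and 0 passed camera with a preset or an estimated inter-gene correlation, with 0 at an unadjusted p under 0.05. Fry called 0 for a common direction (4 at an unadjusted p under 0.05) and 3 for change in either direction: fibroblast and mesenchyme, cytosolic ribosomal proteins and zinc finger genes (adjusted p 0.0128, 0.0128 and 0.0300). After median-ratio scaling the ribosomal and zinc finger lists passed this test and the fibroblast list did not (adjusted p 0.818). With the replicate block it called core pluripotency, the fibroblast and the ribosomal lists (adjusted p 0.0458 each) and not the zinc finger list (0.143), and 0 for a common direction. In these lists RPS10, a small-subunit ribosomal protein, was at 10.7 ± 2.29 and 27.9 ± 8.71 TPM while RPS7 was at 38.8 ± 18.7 and 12.4 ± 5.05 TPM, and neither passed over all genes (limma adjusted p 0.180 and 0.283). Both lay below the ribosomal list's median of 168 TPM in Dokana and 134 in Djasinga. Transcripts without a symbol are not counted, so these sums may be partial. The zinc finger list had 2 of 177 members past the threshold, ZNF302 and ZNF875, and 2 adjusted over the list alone. Adjusted over the list alone, 1 member each passed in the fibroblast list (TWIST2), the mesendoderm and mesoderm list (CER1, its only tested member) and the ribosomal list (RPS10), all of them short of the threshold over all genes.

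Camera's adjusted p was 0.748 for core and primed pluripotency, LIN28/let-7 and microRNA biogenesis, let-7 targets, retroelement restriction, DNA methylation, fibroblast and mesenchyme, imprinted genes, p53 targets, cell cycle, glycolysis, hypoxia and zinc fingers. It was 0.763 for cholesterol synthesis, 0.931 for X-linked genes and ribosomal proteins and 0.935 for the stress responses. With an estimated correlation the adjusted p was 0.956 for each. Lists with fewer than 5 tested members had no test: interferon response and neuroectoderm (4 tested each), Wnt/beta-catenin targets (3), endoderm, histones and ERV-associated transcripts (2 each), mesendoderm and mesoderm, trophoblast and amnion and germ cell (1 each), and naive pluripotency, Y-linked and mitochondrially encoded genes (0 each).

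The genes of the p53 target list were at their lowest in Djasinga replicate 3, a library that stood apart from the others on the first principal component (score 69.1, the others between -36.9 and 12.2). CDKN1A, a cell-cycle inhibitor, was at 49.8, 56.8 and 1.99 TPM in Djasinga replicates 1, 2 and 3, against 42.7, 41.4 and 33.5 TPM in Dokana replicates 1, 2 and 3. DDB2, a DNA repair gene, was at 42.6, 40.4 and 6.35 TPM in Djasinga and between 32.8 and 39.8 TPM in Dokana. MDM2, a ubiquitin ligase, was at 16.6, 15.1 and 5.64 TPM in Djasinga replicates 1, 2 and 3 and at 21.0, 14.4 and 21.9 TPM in those of Dokana. BAX, a cell-death gene, was at 81.7, 61.5 and 28.8 TPM in Djasinga and at 64.2, 82.2 and 64.4 TPM in Dokana. In all 10 tested members of the list Djasinga replicate 3 had the lowest value of the 6 libraries after median-ratio scaling (median log2 deviation from the 6-library median -1.29). On this scale the list was also low in Dokana replicates 3 and 1 (-0.42 and -0.14, with 9 and 8 of 10 members below 0, percentiles 0 and 0.81 of matched random lists). It was high in Dokana replicate 2 and Djasinga replicates 1 and 2 (0.22, 0.40 and 0.26, percentiles 99.86, 99.98 and 99.95). With all 6 libraries the list did not pass camera, which sets it against the other genes. Camera's direction was upward as deposited and downward after median-ratio scaling (adjusted p 0.748 and 0.788). The list's median log2 difference as deposited was nevertheless negative, at -0.50 against -0.29 for the median gene. Without Djasinga replicate 3 the list passed camera at the preset correlation as higher in Djasinga relative to other genes (adjusted p 0.000247, and 0.00817 after median-ratio scaling). It did not pass with an estimated correlation (camera adjusted p 0.996 and 0.849) or by directional fry (0.425 and 0.651). Leaving out any other library gave camera adjusted p between 0.357 and 0.860. In Djasinga replicate 3 all 10 tested glycolysis and all 7 tested hypoxia genes also lay below their 6-library medians (median log2 deviation -0.35 and -0.40, percentiles 0.22 and 0.56 of matched random lists). These percentiles take genes as independent, and 28 of the 108 values of all lists and libraries lay in the outer 5% of random lists, so they describe the libraries and are no test.

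**Figure D3:**
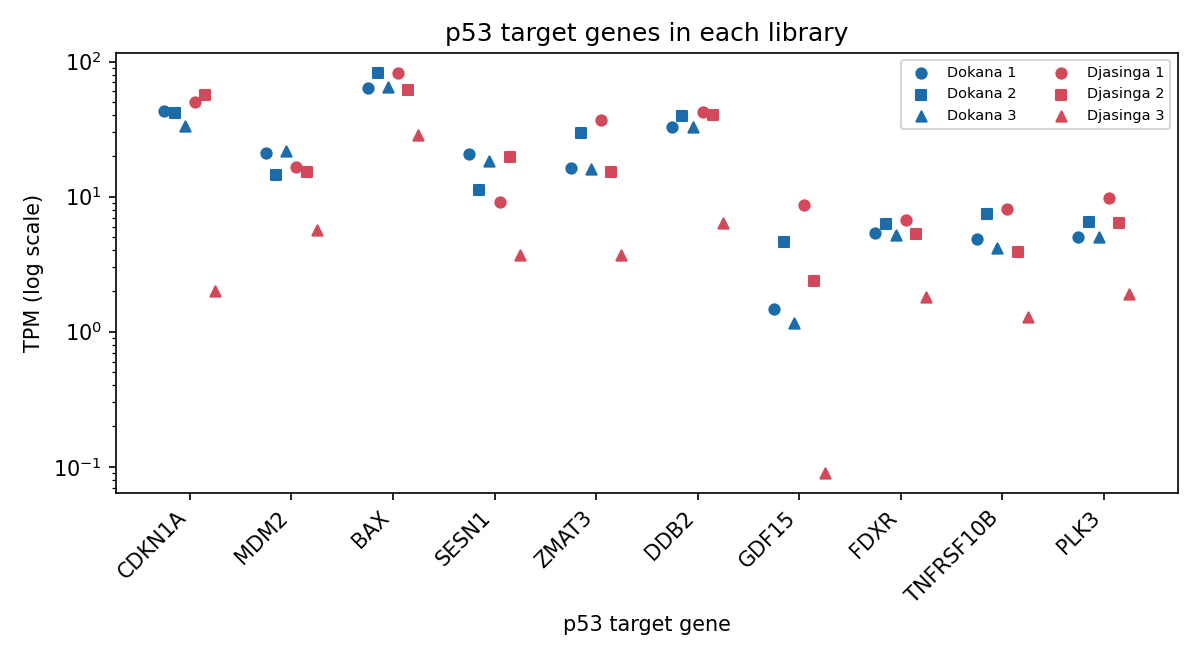
TPM (log scale) of 10 p53 target genes in each library of Dokana (blue) and Djasinga (red). Each symbol is 1 library. Djasinga replicate 3 (red triangles) is the lowest point for every gene, at 1.99 TPM for CDKN1A and 0.0899 TPM for GDF15.

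Of the 29 HERV entries, 9 were listed at 0 in every library, and 7 had a mean of at least 1 TPM in a line. Entry 23 was the most abundant, at 8.42, 5.93 and 6.96 TPM in Dokana replicates 1, 2 and 3 and at 5.96, 5.50 and 3.54 TPM in those of Djasinga. Of 6 entries tested, 0 passed the threshold over all transcripts or adjusted over these entries alone (limma; smallest unadjusted p 0.0978, for entry 23, so 0 were under 0.05). Their summed TPM was 22.6 ± 4.59 in Dokana and 17.1 ± 0.400 in Djasinga (SD, n = 3; two-sided exact permutation p 0.1, the smallest that 3 against 3 libraries allow), and 19.5 ± 1.68 and 19.1 ± 1.00 after median-ratio scaling (exact permutation p 0.9). As deposited, the sum was lower in Djasinga in all 3 pairs of same-numbered libraries (exact paired permutation p 0.25, the smallest possible). The authors' flag marked 5 entries as expressed, of which 1, entry 2, was listed at 0 in every library, and 4 entries without the flag had a mean of at least 1 TPM in a line. Among genes derived from endogenous retroviruses, ERVW-1 (syncytin-1) was at 2.53 ± 0.748 and 2.36 ± 0.225 TPM. Of genes that restrict retroelements, TRIM5 was at 38.3 ± 3.48 and 28.3 ± 10.6 TPM, and 0 of 15 passed the threshold, with 3 lower in Djasinga at an unadjusted p under 0.05 as deposited and 0 after median-ratio scaling (limma).

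A single assembled transcript, STRG.orang_00004509, took 21.9% ± 5.78 of the TPM total in Dokana and 35.6% ± 8.05 in Djasinga (SD, n = 3), with libraries that overlapped between the lines (two-sided exact permutation p 0.2, smallest possible 0.1; log2 difference 0.71, SE 0.23, limma adjusted p 0.249). In pairs of libraries 1, 2 and 3 it took 16.9%, 28.2% and 20.6% in Dokana and 26.7%, 37.7% and 42.4% in Djasinga, more in Djasinga in 3 of 3 pairs (exact paired permutation p 0.25, the smallest possible). The 10 most abundant transcripts of a library held 47.4% to 64.6% of its total.

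**Figure D4:**
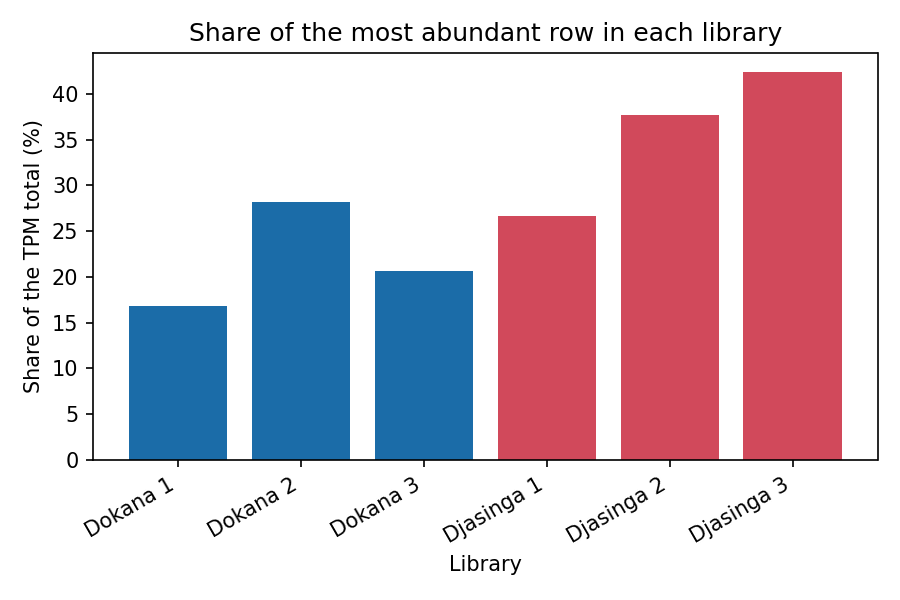
Share of the TPM total (%) taken by the most abundant transcript in each library of Dokana (blue bars) and Djasinga (red bars). It ranges from 16.9% in Dokana replicate 1 to 42.4% in Djasinga replicate 3.

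On average, libraries of a line were slightly more alike than libraries of different lines, and the Dokana pairs carried this. Across the 22561 transcripts, which are not independent replicates, Pearson's r of log2(TPM + 1) averaged 0.931 ± 0.0171 over the 6 pairs within lines and 0.916 ± 0.0128 over the 9 pairs between lines, with ranges that overlapped (0.901 to 0.950 and 0.894 to 0.932). Pairs of Dokana libraries were at 0.942, 0.950 and 0.936. Those of Djasinga were at 0.932, 0.901 and 0.923, about the range between lines. No 2 libraries held identical values. The first principal component, on which Djasinga replicate 3 stood apart, held 32.2% of the variance.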

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

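Fry with the block, fry for change in either direction after median-ratio scaling and other list tests without Djasinga replicate 3 were chosen after seeing the data. So were alternatives combining the block with median-ratio scaling or leaving out the most abundant transcript or small RNA transcripts. Collapsing repeated values and matching accession versions were also chosen then. The 232 transcripts called became 152 with the replicate block, 99 with no filter on low values, 107 with a pseudocount of 0.1, 103 with a filter of 5 TPM, 92 against a fold change of 1.5, 25 and 19 among transcripts with a symbol and protein-coding ones, 29 with the block and median-ratio scaling, and 100 to 211 without 1 library; under the other alternatives the count lay within 1.5 times. The 22 genes with a symbol became 5 with the replicate block, 10 with a pseudocount of 0.1, 9 with a filter of 5 TPM, 8 against a fold change of 1.5, 48 among protein-coding genes alone, 1 with the block and median-ratio scaling, 0 when accessions had to match with their version (limma, 1400 genes tested, 135 at an unadjusted p under 0.05), and 7 to 23 without 1 library. Fewer libraries or genes enter several of these fits; the cause of the other moves was not tested. By camera, list calls were 0, also with the replicate block, outside the cases that follow. With no filter on low values camera called 1 list, naive pluripotency, as higher in Djasinga relative to other genes (adjusted p 0.00668). Its median member was at 0.235 TPM in Dokana and 0.236 in Djasinga, and 0 of 15 passed the filter. Without 1 library camera called 0 to 1 (p53 targets without Djasinga replicate 3, also 1 after median-ratio scaling, and 0 with an estimated correlation or fry). Fry for a common direction called 0 as deposited, with the block, after median-ratio scaling and without Djasinga replicate 3. It was not run under the other alternatives. Fry for change in either direction called 3 lists, 3 with the block (core pluripotency in, zinc fingers out) and 2 after median-ratio scaling. The median TPM of the pluripotency and LIN28/let-7 genes, 21.4 in Dokana and 15.9 in Djasinga, was 17.9 in Djasinga after median-ratio scaling, and Spearman correlations averaged 0.871 within and 0.849 between lines. Of the 16 called transcripts with a symbol that is not a LOC number, 6 held with the block, 9 with median-ratio scaling, 3 without Dokana replicate 3 and 0 with the block and median-ratio scaling together, and none changed sign in any alternative run. TPM keeps no depth, so what depth limits is unknown.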

Other observations

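The tests of the splits of symbol genes and lists and of the immediate-early genes were written before their results were seen; the other tests below, and the choice of genes, came after.

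Genes of sterol synthesis, the cell cycle and hypoxia differed between libraries of a line. After median-ratio scaling, the median of the 11 tested genes of cholesterol synthesis lay low in Dokana replicate 2 and Djasinga replicate 1 (median log2 deviation from the 6-library median -0.55 and -0.93, percentiles 0.01 and 0 of 10000 random lists matched on expression). Below 0 were 11 of 11 genes and 10 of 11, the exception being PMVK at 1.59 TPM in Djasinga replicate 1. In Djasinga replicate 1, all 11 tested cell cycle genes also lay below the median (median -0.51, percentile 0), as did 10 of 11 in Dokana replicate 2 (-0.18, percentile 1.03). The 7 tested hypoxia genes, among them PDK1 and VEGFA, had medians of 0.45 in Dokana replicate 1 and 0.39 in Djasinga replicate 2 against -0.40 in Djasinga replicate 3, -0.31 in Djasinga replicate 1, -0.15 in Dokana replicate 2 and 0.15 in Dokana replicate 3. Percentiles of random lists take genes as independent, and 21 of 96 values of the lists without p53 targets lay in the outer 5% of random lists, so they describe the libraries and are no test.

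When protein-coding genes were tested without other classes, limma called 48 of 5089. CNMD, which encodes chondromodulin, was at 23.8 ± 3.71 TPM in Dokana and 8.48 ± 2.56 in Djasinga (SD, n = 3; limma adjusted p 0.00579), the adhesion molecule ALCAM at 17.4 ± 0.522 and 7.59 ± 2.20 TPM (0.0280) and the tight-junction gene CLDN11 at 34.5 ± 2.56 and 18.1 ± 2.00 TPM (0.0477). FST, the activin antagonist follistatin, was higher in Djasinga, at 0.753 ± 0.518 and 2.95 ± 1.27 TPM (0.0314). After median-ratio scaling 3 of the 48 remained, ZNF302, PDPK1 and LOC100431578, all higher in Djasinga, while CNMD, ALCAM, CLDN11 and FST did not (adjusted p 0.209, 0.320, 0.250 and 0.157). Transcripts at 0 throughout one line and at 1 TPM or more throughout the other numbered 49, 36 of them in Dokana alone. The other splits of the libraries, each of which mixes the lines, gave 14 to 26. Grouped by chromosome, median gene changes after median-ratio scaling lay between -0.06 and 0.06 for 24 groups.

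Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave 232 transcripts (highest other 8) or 22 genes (highest other 13). For the lists the real count was 0, which all 10 splits reach by necessity, so it tests nothing (highest other 6 at camera's preset correlation, and 0 with an estimated one). With 10 splits no share under 0.05 is possible. Each other split also mixes the lines, so a difference between the lines widens its within-group spread and lowers its count. The gap between the counts therefore does not measure how far the real one exceeds chance.

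After median-ratio scaling, the p53 target genes were low in Djasinga replicate 3 (median deviation -1.29) and, by less, in Dokana replicate 3 (-0.42, 9 of 10 below 0). As deposited, members went both ways in Dokana replicate 3. MDM2 was the highest of the 6 libraries there (21.9 TPM), and CDKN1A lay below Dokana replicates 1 and 2 (33.5 TPM against 42.7 and 41.4). Djasinga replicate 3 lay apart on the first principal component (score 69.1, the others between -36.9 and 12.2). Its glycolysis and hypoxia genes were low too (median -0.35 and -0.40). The scaling or composition of Djasinga replicate 3 is argued against: as deposited, 1114 other genes of the same expression had a median deviation of -0.13 there, and all 10 list members lay below percentile 5 of these genes, -0.84. A Dokana library under that label is argued against too: 85.2% of the transcripts called without it lay on the Djasinga side. This fell short of the 90 set beforehand, which Djasinga replicates 1 and 2 missed by more (81.5% and 81.7%). The comparison with these replicates was added after the value was seen. Dokana libraries lay on their own side in 93% to 95.4%. The check only places a library between the means of these 2 lines, so it cannot exclude a mixed library. A weaker p53 response stays open: a second list of 8 tested p53 targets, among them POLH, a DNA polymerase (1.35 TPM in Djasinga replicate 3, 6.02 to 7.30 in the other libraries), had a median of -0.49 in Djasinga replicate 3 and -0.14 in Dokana replicate 3, but its percentiles of 0.07 and 3.04 are no test either. A batch shared by the libraries numbered 3 cannot be told apart, since Dokana replicate 3 was low after scaling but by under 0.5 times as much. Nor can less handling stress, with 1 immediate-early gene tested (NR4A1, deviation -0.086).

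Most values were lower in Djasinga, with a median of -0.27. Without the most abundant transcript and with the rest rescaled to the same sum, the median was -0.054, so the larger share of that transcript in Djasinga may account for most of the shift. Dokana replicate 3 alone is argued against, since the median without it was -0.17. A difference between the lines in that transcript stays open: it did not pass the threshold (log2 difference 0.71, SE 0.23, limma adjusted p 0.249; exact permutation p 0.2).

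Called transcripts of named genes and small RNAs had candidate technical explanations. Reads moving between transcripts of a gene cannot be told apart from a change of the gene: the others moved the opposite way by at least 0.5 in 8.33% of the 12 called transcripts with others of their gene, 1 in all (POLR1H), but only 9 of the 12 could have reached this in a full transfer, and only these 12 of the 44 called with a symbol had others named. A recovery that differed alike for all small RNAs is argued against. After median-ratio scaling, the median log2 change was -0.014 over 505 snRNA and 0.023 over 530 snoRNA genes tested. Of the 15 called snRNA and snoRNA genes, 46.7% went against the majority direction (snRNA 6 higher and 4 lower, snoRNA 1 higher and 4 lower). Reads split among copies could also give both directions, so those of the called genes do not decide it. Reads shared between near-identical copies cannot be told apart from a change of single copies: summed snRNA TPM differed by -0.14 on the log2 scale, but only 50.6% of RefSeq transcripts have a name. A genetic difference between the lines stays open and was not tested.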
